A study of Drosophila melanogaster with 3 samples.

How the data were processed

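Transcription factor ChIP-seq was done on whole embryos of a transgenic Drosophila melanogaster line that expresses CG30403 with a C-terminal green fluorescent protein, aged 0 to 24 hours and of mixed sex. Per the labels, chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against the tag, in 3 biological replicates. A shared control was used, per the deposited text notes; it is not analysed here. The aligner, the peak caller and the threshold of the irreproducible discovery rate (IDR) procedure are not given in the sources used here.

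The authors deposited 10 region lists in narrowPeak format: for each replicate, and for the pooled replicates, peaks with background regions as input for IDR on builds dm3 and dm6, and for the group the optimal IDR peaks on each build. The group's regions were called on the pooled alignments of the 3 replicates, per the deposited text notes. No list is longer than 30000 regions, and lists reach far into weak regions, so that their lengths were not compared as counts of binding sites. The signal value of each region is a score deposited by the authors from their peak caller, with no stated scale. The second value is the −log10 of a q value, deposited by the authors; it has a single value over the whole optimal list (4.23 on dm6) and was not used for ranking. The deposited summit offset gives the distance in bp from the region start. Several regions can overlap and carry a summit each. Depth is unknown, since the lists carry no read counts, and intervals given here cover counting of peaks or genes only.

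All lists were ranked by signal value within each list. Replicates were compared with lists of equal length, the 7827 strongest regions of each, and an overlap of at least 1 bp counted as shared. Chance was measured by shifting lists circularly along each arm 1000 times; these shifts can place regions in assembly gaps and repeats that no read could map to. Gene positions came from Ensembl release 115 and sequence from the Release 6 assembly, which has the arm names of dm6, and no dm6 region runs past an arm end. No coordinates were converted between builds, and dm3 lists were compared only as counts per arm and among themselves. A gene was called promoter-bound when an optimal summit lay within 500 bp of any annotated TSS. The 13945 protein-coding genes on 2L, 2R, 3L, 3R, 4 and X were the background of the gene lists.

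Gene lists were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over the 33 lists; odds ratios have 0.5 added to each cell. The share that a count of 0 allows is 3 counts of the total; the plot of the lists shows two-sided 95% exact intervals, whose upper ends lie slightly higher. The lists and motifs were fixed in advance, partly by patterns of gene symbols. 1 symbol of the gut list matched no gene. Motifs, written as consensus sequences and searched on both strands, were counted by presence within 50 bp of the summit and in flanks 200 to 250 bp away on both sides, with two-sided exact McNemar tests. 7-mers were ranked on 2L and 3L and tested on the other arms. Location classes were assigned by summit, in the order promoter, 5' untranslated region, coding exon, 3' untranslated region, noncoding exon, intron, intergenic. Bootstrap intervals of GC differences used 1000 resamples of peaks.

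The rule for named items was fixed before the data were examined: CG30403; the 20 protein-coding genes with the strongest promoter peaks found in every replicate, nearest TSS first; the 3 strongest bound members of each list past the threshold; if wanted, further bound members of the Hox, gap, pair-rule, architectural and Polycomb and Trithorax lists; the 5 strongest peaks over 500 bp from a TSS; and the 5 motifs and 5 7-mers with the largest centre-to-flank ratio. Ssl1, CG9004, Cdc37, Cyp1, Cp190 as a member of the chorion list, AAAATAT, TAAAAAA, AAAAATT, and the GAGA, CAGCTG, CA repeat and Bicoid motifs were named after their values were seen.

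Alternatives planned in advance were a reciprocal overlap of 50%, summits within 100 bp, shorter lists, promoter windows of 250 and 1000 bp, any overlap with the window, motif windows of 25 and 100 bp, genes with isolated TSSs, 20 kb blocks counted once, other discovery arms and leaving out each replicate. Chosen after seeing the data were 1 summit per merged region and dinucleotide-preserving shuffles of the peak centres, because the flanks turned out to differ from the centres in composition, leaving out the histone list or the dm3 regions outside the arms, and the comparison of location classes among summits outside promoters. Ratios to shuffles use the mean of 20 shuffles, and the exact McNemar test uses the first.

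The procedures were tested on simulated data. A planted overlap of 50% was measured as 51.2% with 2.79% by chance; 4 of 4 planted gene lists and 0 of 30 unplanted lists were called over 13945 genes. The simulated lists were longer than the shortest real ones and drawn at random, so they say nothing about small lists or clustered genes. A motif planted in 5.03% of 7827 random centres was found in 5.05%, with 0 of the other 20 motifs called. Its 4 7-mers were called with 7 that overlap its edges and 0 others, and no 7-mer was called without planting. Centres at random positions lack the GC difference between the real centres and their flanks. The simulation therefore says nothing about motif and 7-mer calls that this difference can give. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.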

Results

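Binding of the uncharacterised Drosophila melanogaster protein CG30403 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole embryos aged 0 to 24 hours. The flies carried CG30403 fused at its C terminus to enhanced green fluorescent protein, and the chromatin was precipitated with an antibody against that tag. The samples form 1 group of 3 biological replicates, and embryos of both sexes were pooled. For each replicate the authors deposited a ranked list of peaks together with background regions, and for the group a pooled list and a final list of reproducible ("optimal") peaks. The optimal list held 7827 regions on build dm6, with a median width of 484 bp, which merge into 7082 separate regions. The dm6 replicate lists held 29373, 30000 and 30000 regions for replicates 1, 2 and 3. Read depth is unknown, because the region lists carry no read counts. The signal values are the authors' own and were used only to rank peaks within a list.

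The first question was how far the 3 replicates gave the same sites. The strongest sites did so closely: the peak in overlapping introns of HmgD and HmgZ on 2R ranked first in every replicate, and the promoter peak of CG14100 ranked 3, 2 and 3 in replicates 1, 2 and 3. Of the 7827 strongest regions of replicate 1, 86.9% were overlapped by at least 1 bp by those of replicate 2 and 84.7% by those of replicate 3, and 86.6% of those of replicate 2 by those of replicate 3. Circular shifts of a list along the chromosomes gave 4.79%, 4.87% and 4.39% on average and at most 19.5% (one-sided permutation p = 0.001 for each pair, the smallest that 1000 shifts can give). Of the 7827 optimal peaks, 5791 (74.0%) were overlapped by the top list of every replicate; the optimal list was itself selected for reproducibility among these replicates, so this share describes the list and is no independent test. The shared share was 99.4% in the strongest 1957 optimal peaks (1946 peaks) and 28.0% in the weakest 1956 (548 peaks). Replicate 1 covered 82.8% of the optimal peaks, replicate 2 covered 93.0% and replicate 3 covered 91.9% (mean 89.2% ± 5.62, SD, n = 3). With both directions of each pair averaged, the shared share of the replicate top lists was 83.8% ± 2.55 (SD over 3 pairs), from 81.3% for replicates 1 and 3 to 86.3% for replicates 2 and 3. Spearman correlations of the signal values were 0.83, 0.76 and 0.84 for replicates 1 and 2, 1 and 3, and 2 and 3. They cover only merged optimal regions found in both full replicate lists. These regions were selected for reproducibility, so the correlations are no independent test either, and regions are not independent replicates.

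The second question was where in the genome the tagged protein was found. Peak summits were concentrated at promoters and nearly missing from coding exons outside promoters. Of the 7827 optimal summits, 3601 lay within 500 bp of a transcription start site (TSS) of a protein-coding gene, 46.0% (95% exact interval 44.9 to 47.1%). Shifted summits gave 11.5% on average and at most 13.4%, so promoters held 4.02 times the chance share (one-sided permutation p = 0.001, the smallest possible; adjusted over 7 classes 0.0012). After the data were seen, the other classes were compared among the 4226 summits outside promoters, since shares of all summits add up to 100%. Introns held 2831 of these, 66.99% against 45.1% by chance, and noncoding exons 127, 3.01% against 1.80%. Only 11 lay in coding exons (0.26% against 15.7%) and 61 in 3' untranslated regions (1.44% against 5.15%; one-sided permutation tests, adjusted p = 0.0015 for each of these 4 classes). Intergenic DNA held 1162 (27.5% against 31.3%, adjusted permutation p = 0.0072) and 5' untranslated regions 34 (0.805% against 0.905%, adjusted permutation p = 0.22). As shares of all 7827 summits, introns lay below chance instead (36.17% against 39.97%, adjusted permutation p = 0.0012). The 5' untranslated regions did too (0.434% against 0.801%, adjusted permutation p = 0.0012). Noncoding exons then showed no detected excess (1.62% against 1.59%, adjusted permutation p = 0.42). The promoter share was 46.3% ± 0.14 (SD, n = 3) in the replicate top lists. Promoter summits lay a median of 122 bp from the nearest TSS.

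The promoter share was higher among stronger peaks. It was 74.0% (95% exact interval 64.3 to 82.3%) in the 100 strongest optimal peaks, 65.5% (62.5 to 68.4%) in the 1000 strongest and 53.2% (51.7 to 54.8%) in the 4000 strongest. The replicate lists gave 64.9% ± 1.97 for the 1000 strongest and 52.9% ± 1.39 for the 4000 strongest (SD, n = 3).

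**Figure D1:**
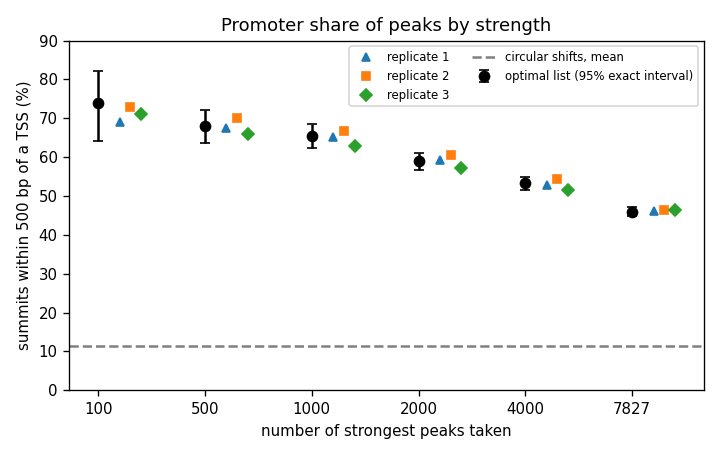
Share of peak summits within 500 bp of a protein-coding TSS (y axis, percent) for growing numbers of the strongest peaks (x axis), in the optimal list (black, 95% exact interval) and the 3 replicates (coloured points); the dashed line is the mean of the circular shifts. The share falls from 74.0% for the 100 strongest peaks to 46.0% for all 7827, above the shifted mean of 11.5% throughout.

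At the gene level, 4205 of 13945 protein-coding genes (30.2%, 95% exact interval 29.4 to 30.9%) had an optimal summit within 500 bp of a TSS. The replicate top lists gave 4116 ± 172 genes (SD, n = 3), and 3307 genes were promoter-bound in the optimal list and in each of the 3 replicates. The 20 genes named by strength had signal values from 2664 to 5654 and summits at most 341 bp from their TSS. Mitochondrial ribosomal proteins among them were mRpL41 (FBgn0034001; 2R:15217526-15218042, signal 3900) and mRpL23 (FBgn0035335; 3L:2373373-2373839, signal 2777, a promoter shared with CG9004). The promoter peak named for Art3 (FBgn0038306; 3R:15229284-15229803, signal 3949) was shared with mRpS10, and that of CenG1A with mRpS23. PNPase, a polynucleotide phosphorylase (FBgn0039846; 3R:31404421-31404888), had a signal of 3167. All coordinates are 1-based on dm6. The strongest was CG14100 (FBgn0036889; 3L:19590351-19590868, summit 97 bp from the TSS, signal 5654), followed by Ugalt, a UDP-galactose transporter (FBgn0024994; X:2703640-2704164, signal 4573). Chro, which encodes the chromosomal protein Chromator (FBgn0044324; 3L:22878647-22879155, signal 3853), ranked 8 in all 3 replicates and shared its promoter peak with Ssl1, a subunit of the general transcription factor TFIIH. The others were px, Tcs5, CG5611, CG31145, CenG1A, Tina-1, Fkbp14, larp, CG18549, CG8320, CG1888, Pdrg1 and PTPMT1. For 9 of the 20, another protein-coding gene had a TSS within 500 bp of the same summit, so the peak does not tell which gene it belongs to. Each of the 20 peaks ranked 53 or better in every replicate.

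The 5 strongest peaks more than 500 bp from any protein-coding TSS were mostly intronic. The peak that ranked first overall (2R:21703019-21703753, signal 6456) lay in overlapping introns of HmgD and HmgZ, which encode high mobility group DNA-binding proteins, 567 bp from a TSS of HmgZ. The second (2L:480536-481394, signal 5674) lay in an intron of ush, which encodes the GATA cofactor U-shaped, 1382 bp from the TSS of cbt. Introns of CG11050 (2L:6612412-6612954, signal 4762) and CG32772 (X:4909971-4910683, signal 3495) held 2 more, and an exon of the long noncoding RNA Vinr (X:12750775-12751741, signal 3577) held another, 5037 bp from the nearest protein-coding TSS.

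The third question was which gene groups had bound promoters. Ribosomal proteins, aminoacyl-tRNA synthetases and translation factors were bound more often than other genes, as were architectural proteins and Polycomb and Trithorax genes. Chemosensory receptors, cuticle proteins, seminal fluid proteins and cytochrome P450 genes were bound less often. Of 33 preset lists, 18 differed from the remaining protein-coding genes at an adjusted p under 0.05 (two-sided Fisher's exact tests, Benjamini-Hochberg over the 33 lists), 9 upwards and 9 downwards; 19 had an unadjusted p under 0.05. One of the 9 downward lists, the histones, could not have come out otherwise. Without it, 17 of 32 lists passed, 9 upwards and 8 downwards. Some promoter peaks were counted for members of different lists, so the lists called upwards are not fully separate evidence.

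Among the cytosolic ribosomal proteins, 72 of 92 genes were bound (78.3%; 75.4% ± 3.49 over replicates, SD, n = 3), against 29.8% of other genes (log2 odds ratio 3.06, adjusted p = 2.8e-20 by Fisher's exact test). RpL34b, RpS27 and RpL7 had the strongest promoter peaks of this group, with signals of 1432, 1132 and 1091. The mitochondrial ribosomal proteins followed with 45 of 73 bound (61.6%, log2 odds ratio 1.90, adjusted exact p = 1.7e-07), led by mRpS10, mRpL41 and mRpS23. Aminoacyl-tRNA synthetases, which charge tRNAs, had 19 of 33 bound (57.6%, log2 odds ratio 1.64, adjusted exact p = 0.0035), led by SerRS, GluProRS and IleRS. Translation factors had 28 of 53 bound (52.8%, log2 odds ratio 1.38, adjusted exact p = 0.0031), led by eIF6 (signal 2377), eIF4EHP and eIF3c.

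Genes of chromatin and transcription were also bound more often. Of 16 architectural and insulator proteins, 11 were bound (68.8%, 66.7% ± 7.22 over replicates, SD, n = 3; log2 odds ratio 2.28, adjusted p = 0.0049, Fisher's exact test): Chro, Cp190, pzg, Trl, M1BP, Dref, BEAF-32, pita, su(Hw), CTCF and mod(mdg4). Of 22 Polycomb and Trithorax group genes, 13 were bound (59.1%, log2 odds ratio 1.72, adjusted exact p = 0.012), with the highest signals at ph-p (2492), brm (1593) and Sfmbt (747). The general RNA polymerase II factors and Mediator subunits had 23 of 50 bound (46.0%, log2 odds ratio 0.99, adjusted exact p = 0.036), led by MED27, MED30 and MED17. The replication and cell cycle list had 23 of 42 bound (54.8%, log2 odds ratio 1.49, adjusted exact p = 0.0035), led by Cdc16, Cdk12 and CycE. This list was built from gene symbols and also took in genes of other kinds. Examples are Cdc37, a chaperone partner, and Cdk12, a transcriptional kinase, and they are not the only ones. The vacuolar ATPase had 17 of 33 bound (51.5%, log2 odds ratio 1.30, adjusted exact p = 0.025), led by Vha100-2, Vha16-5 and Vha68-1.

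Odorant, gustatory and ionotropic receptors were the most depleted group by p, with 1 of 179 bound (0.559%, log2 odds ratio -5.71, adjusted p = 2.8e-25, Fisher's exact test); the bound member was Ir60e. No cuticle protein gene of 121 was bound, which allows a share of up to 2.48% (log2 odds ratio -6.73, adjusted exact p = 2.2e-18). Seminal fluid proteins had 1 of 49 bound (Sfp26Ad, log2 odds ratio -3.81, adjusted exact p = 4.8e-06), cytochrome P450 genes 9 of 85 (10.6%, log2 odds ratio -1.81, adjusted exact p = 0.00012, led by Cyp6u1, Cyp310a1 and Cyp6v1) and glutathione S-transferases 4 of 35 (11.4%, log2 odds ratio -1.60, adjusted exact p = 0.03, led by GstE13, GstT4 and GstD1). The 9 bound members of the cytochrome P450 list include Cyp1, a cyclophilin gene taken in by its symbol. None was bound among 17 dorsoventral patterning genes (which allows up to 17.6%; log2 odds ratio -3.92, adjusted exact p = 0.008), and none among 15 antimicrobial peptide genes or 15 gut genes (which allows up to 20%; log2 odds ratio -3.74, adjusted exact p = 0.018 each). With a window of 1000 bp, 2 of the 17 dorsoventral genes were bound and that list did not pass (log2 odds ratio -1.68, adjusted exact p = 0.11). That window also gave bound cuticle protein genes (4 of 121), receptors (5 of 179), seminal fluid proteins (3 of 49) and antimicrobial peptides (1 of 15). Those lists still passed as bound less often. Replication-dependent histone genes also had 0 of 111 bound (adjusted exact p = 5.7e-17), but all 111 lie in the repeated cluster at 2L:21416953-21541681 (dm6), where the pooled list with background has no region within 500 bp of any of them, so that cluster gives no measurement.

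Gap, pair-rule and Hox genes did not pass the threshold with the window of 500 bp; with 1000 bp the gap genes did (0 of 10 bound, log2 odds ratio -3.44, adjusted exact p = 0.038). None of 10 gap genes (which allows up to 30%; adjusted exact p = 0.067) and 9 pair-rule genes (up to 33.3%; adjusted exact p = 0.094) was bound in the optimal list, and 2 of 8 Hox genes were (Dfd, signal 255, and Antp, signal 186; adjusted exact p = 1). The remaining lists that missed the threshold were the proteasome (21 of 48), germline genes (7 of 17), oxidative phosphorylation (33 of 86), ecdysone response (4 of 12), heat shock proteins (8 of 24), segment polarity (4 of 12), the E(spl) complex (3 of 11), muscle (4 of 18), glial (2 of 12), neuronal (2 of 21) and fat body genes (1 of 11). The chorion, vitelline and yolk list had 1 of 16, and that member was Cp190, an insulator protein taken in by its symbol.

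Fewer lists passed when genes with close neighbours were left out, which also left fewer members. Among the 7960 genes whose TSSs lie over 1000 bp from those of every other gene, 1341 (16.8%) were bound, and only 3 lists passed: cytosolic ribosomal proteins (24 of 34, adjusted exact p = 8.8e-11), receptors (0 of 144) and cuticle proteins (0 of 106). The log2 odds ratio fell for mitochondrial ribosomal proteins (0.72, from 1.90), aminoacyl-tRNA synthetases (0.93, from 1.64) and general RNA polymerase II factors and Mediator (0.10, from 0.99), and moved toward 0 for cytochrome P450 (-0.79, from -1.81) and glutathione S-transferases (-0.38, from -1.60). It was no smaller for architectural proteins (2.79, 5 members), Polycomb and Trithorax genes (2.31, 10 members), replication and cell cycle genes (2.13, 15 members) and the vacuolar ATPase (1.36, 18 members), and 1.35 for translation factors (24 members). Seminal fluid proteins (0 of 24, -3.32) and dorsoventral genes (0 of 16, -2.75) had no bound member and no call.

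The calls also depended on how many of the peaks were used. With the stronger 50% of peaks, lower log2 odds ratios and no call were obtained for aminoacyl-tRNA synthetases (0.86), Polycomb and Trithorax genes (0.98), replication and cell cycle genes (0.57), the vacuolar ATPase (0.66) and translation factors (0.97). General RNA polymerase II factors and Mediator had 1.09 and no call. Calls also ended for dorsoventral genes (-3.11), gut genes and antimicrobial peptides (-2.93 each), with 0 bound as before, and for glutathione S-transferases (-1.19). With the 1000 strongest peaks the architectural proteins, receptors and cuticle proteins passed, the unmeasured histones aside, and the log2 odds ratio of the cytosolic ribosomal proteins was 0.78 (adjusted exact p = 0.37). Few members were bound by so few peaks, and the other lists called upwards with all peaks went both ways: Polycomb and Trithorax genes (2.09) and general RNA polymerase II factors and Mediator (1.44) had higher ratios than with all peaks. Aminoacyl-tRNA synthetases (1.38), mitochondrial ribosomal proteins (1.32), translation factors (1.13), replication and cell cycle genes (0.66) and the vacuolar ATPase (0.10) had lower ones. With genes of one 20 kb block counted once, histones no longer passed, nor did gut genes (log2 odds ratio -3.31, 11 members), antimicrobial peptides (-3.04, 9 members) and glutathione S-transferases (-1.22, 15 members), which leaves 14 lists. The lists made without a replicate hold top regions of 1 remaining replicate shared with the other. They are other peak sets than the optimal list, so a lost call cannot be credited to the replicate alone. With each of them the calls of the general RNA polymerase II factors and Mediator ended (log2 odds ratios 0.98, 0.76 and 0.84 without replicates 1, 2 and 3, against 0.99 in the main test). The calls of the vacuolar ATPase (1.18, 1.14 and 1.11) and the glutathione S-transferases (-1.38, -1.24 and -1.28) ended too. Translation factors lost theirs without replicate 1 (0.95) or 3 (0.94), Polycomb and Trithorax genes without replicate 2 (1.32) or 3 (1.28), and aminoacyl-tRNA synthetases (1.14) and replication and cell cycle genes (1.03) without replicate 2.

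**Figure D2:**
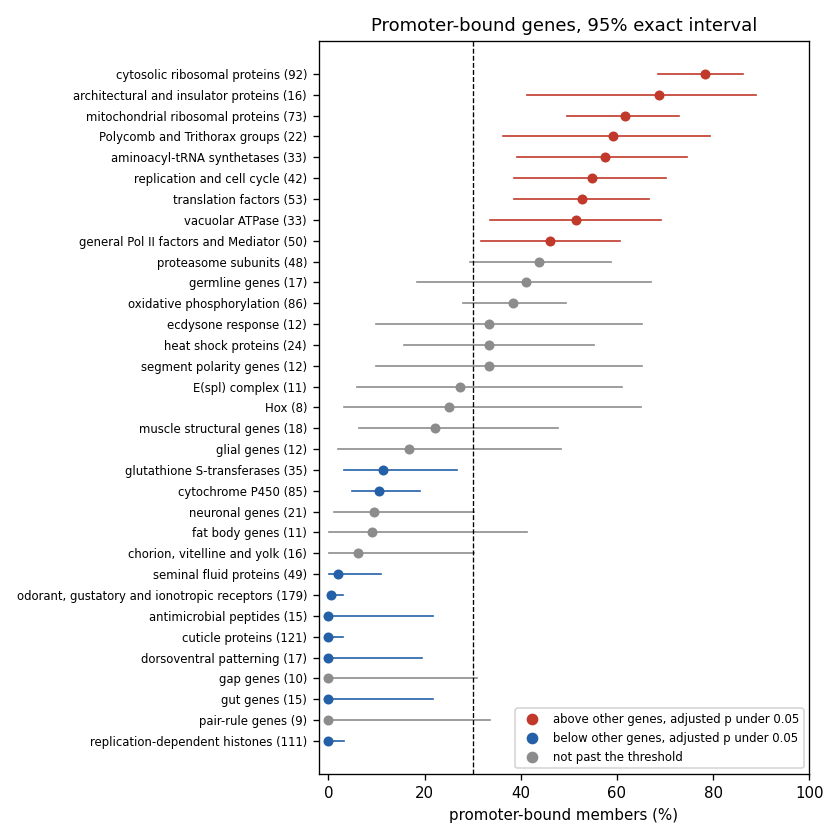
Promoter-bound share (x axis, percent) of each of 33 gene lists (y axis, members in brackets), with 95% exact intervals; the dashed line is the share over all protein-coding genes, 30.2%. Red and blue mark the 9 lists above and the 9 below other genes at an adjusted p under 0.05, the unmeasured histones among the latter, and grey the rest; the points run from 78.3% for cytosolic ribosomal proteins to 0 for cuticle proteins and histones.

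The fourth question was which DNA sequences marked the summits. Summits lay in AT-rich DNA. The GC content of the central 100 bp averaged 33.1% in the optimal peaks and 44.5% in flanks 325 to 425 bp away, a difference of -11.4 percentage points (95% bootstrap interval -11.7 to -11.2). The difference was -10.8 ± 0.957 (SD, n = 3) in the replicate top lists and was larger in the 1956 strongest peaks (-14.1, interval -14.6 to -13.6) than in the 1956 weakest (-9.48, interval -10.0 to -8.97). All of the 20 7-mers taken from peaks on 2L and 3L passed on the 4779 held-out peaks of 2R, 3R, X and 4 (exact McNemar tests, largest adjusted p = 1.6e-17), and all 20 consisted of A and T only. The largest centre-to-flank ratios were 2.68 for AATATTA (9.37% of centres against 3.49% of flanks), 2.51 for TAATATA, 2.35 for TTTAAAA, 2.29 for ATATTAA and 2.28 for TAAAATA. Against shuffled copies of the same centres that keep their dinucleotides, 8 of the 20 remained more frequent at an adjusted p under 0.05, with AAAATAT highest at 1.54 times; AATATTA, TTTAAAA and TAAAATA were among the 8, TAATATA and ATATTAA were not. Less frequent than in the shuffles were 2 of the 20, TAAAAAA (0.83 times, adjusted exact p = 0.0011) and AAAAATT (0.728 times, adjusted exact p = 3.5e-08).

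**Figure D3:**
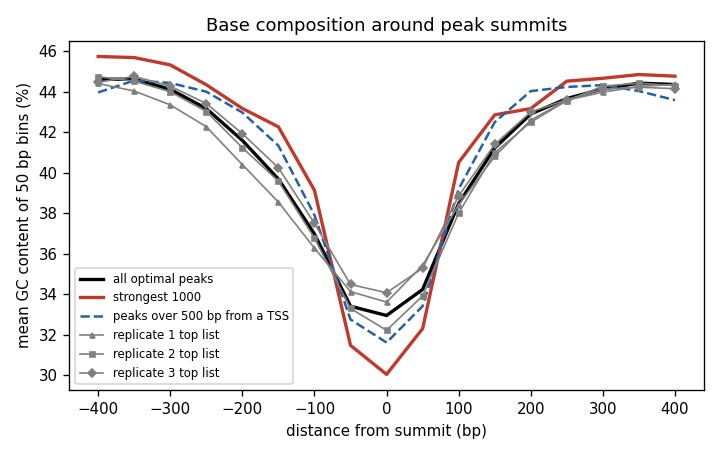
Mean GC content of 50 bp bins (y axis, percent) by distance from the summit (x axis, bp) for all optimal peaks, the 1000 strongest, peaks over 500 bp from a TSS and the top lists of the 3 replicates. All curves dip at the summit; the central 100 bp average 33.1% GC in all optimal peaks and 30.2% in the 1000 strongest.

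Of 20 preset sequence motifs, 16 differed between the central 100 bp and the flanks (exact McNemar tests, adjusted p under 0.05), 10 toward the centre and 6 toward the flanks. The CTCF site had the largest ratio, 5.08 (1.69% of centres against 0.332% of flanks, adjusted exact p = 3.3e-18; 1.37% ± 0.579 of centres over replicates, SD, n = 3). The DNA replication-related element DRE (TATCGATA), bound by Dref, had a ratio of 3.19 (2.33% against 0.728%, adjusted exact p = 1.3e-16), and core promoter motif 7 one of 2.41 (adjusted exact p = 3.0e-10). The TATA box had 1.95 (8.98% against 4.61%, adjusted exact p = 5.4e-26) and the Su(Hw) site 1.94 (0.447% against 0.23%, adjusted exact p = 0.034). The flanks differ from the centres in base composition, and against the shuffled centres the TATA box was no longer enriched (8.46% against 8.16%, adjusted exact p = 0.98), while CTCF (21.6 times), DRE (12.3 times), motif 7 (2.87 times) and Su(Hw) (2.75 times) were. Against the shuffles 14 motifs passed, 12 above and 2 below. The GAGA motif (2.46 times), CAGCTG (2.69 times) and the CA repeat (2.66 times), counted toward the flanks above, were more frequent in centres than in shuffles, and the Bicoid motif, counted toward the centre, was less frequent (0.755 times). With the 1000 strongest peaks the TATA box alone of these 5 passed. The log2 ratio of discordant peaks then fell for CTCF (0.79, from 2.41) and motif 7 (0.25, from 1.30), turned negative for DRE (-0.21, from 1.76) and was higher for Su(Hw) (1.87, from 0.94); the Su(Hw) call also ended with the stronger 50% of peaks (0.77), with peaks in all 3 replicate lists (0.91), with a motif window of 25 bp (0.52) and without replicate 2 (0.85) or 3 (1.03).

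At the locus of CG30403 itself, peaks were present but not among the strongest. The gene (FBgn0050403; 2R:21709895-21711613, minus strand, dm6) is nested in HmgD. The highest region within 1 kb ranked 2159, 2064 and 1908 in replicates 1, 2 and 3 (mean 2044 ± 127, SD, n = 3) and 1928 in the pooled list, with a pooled signal of 416. Its pooled summit at 2R:21709699 lay 196 bp beyond the 3' end of the gene. With no margin around the gene the mean rank was 11785. This mean joins unlike ranks. The region ranked 2159 in replicate 1 overlaps the gene itself, whereas those given for replicates 2 and 3 end before it, which leaves weaker regions there. The promoter of CG30403 was not bound, whereas the strongest peak of the genome lay 6498 bp from the gene. The density of pooled regions within 20 kb of CG30403, that peak left out, was at percentile 99.0 of all protein-coding genes (0.503 per kb against a median of 0.213).

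**Figure D4:**
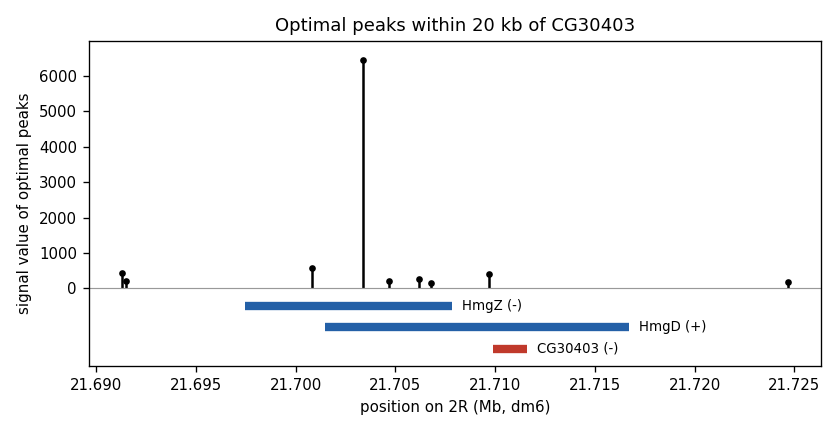
Signal values (y axis) of the 9 optimal peaks within 20 kb of CG30403, at their summits on 2R (x axis, Mb, dm6), above the extents of HmgZ, HmgD and CG30403 with their strands. The peak of signal 6456 lies where HmgD and HmgZ overlap, and the peak nearest to CG30403 has a signal of 416.

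Because embryos of both sexes were pooled, X was compared with the other arms. On X, 701 of 2196 protein-coding genes were promoter-bound (31.9%), against 3504 of 11749 elsewhere (29.8%; log2 odds ratio 0.14, p = 0.051, two-sided Fisher's exact test). The direction depended on the peaks and the window used, as given under the dependence on processing. With the 1000 strongest peaks the log2 odds ratio was -0.70 (exact p = 2.2e-06). Optimal peaks per Mb were 64.7 on X, 60.3 on 2L, 58.0 on 3L, 58.0 on 3R, 54.1 on 2R and 20.03 on chromosome 4. Chromosome 4 had 15 of 80 genes bound (18.8%, 95% exact interval 10.9 to 29.0%).

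The same libraries were also deposited against build dm3, with 7526 optimal regions against 7827 on dm6. The share of optimal peaks per arm differed between the builds by at most 0.0844 percentage points, on 3L (20.7% on dm3, 20.8% on dm6). Without the 3 dm3 regions outside the arms the largest difference was on X, -0.0823 points (dm6 minus dm3). The strongest peak had a signal of 6456 on both.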

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

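All tests of explanations for the base composition and for the tagged locus were chosen after the result was seen; those for the location of the summits were not.

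Regions outside the 6 main arms appear in the dm3 lists, and no comparison examined them, although the 3 in the optimal list are part of the total behind the dm3 shares per arm; their counts in the longer lists exceed the 3 that a count of 0 allows, with 49 in the pooled list, and 80, 82 and 29 in the lists of replicates 1, 2 and 3. They lie on scaffolds of heterochromatin and of unplaced sequence, and the best ranks 6256 in the pooled list; a control list is not used here.

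The first pattern is the AT-rich centre of the peaks, and the design has no second group, so no biological explanation was tested. The base composition of promoters is argued against: the 2683 peaks over 2000 bp from any protein-coding TSS have a centre-minus-flank GC difference of -12.7 percentage points (95% interval -13.1 to -12.3), beyond that of promoter peaks (-10.7). A preference of the libraries for AT-rich DNA would shape weak regions too, but the 10000 weakest pooled regions have a difference of only -0.749 (interval -0.973 to -0.501). Their flanks are also lower in GC than those of the optimal peaks (41.6% against 44.5%). How well summits of such weak regions are placed is unknown, so this does not exclude such a preference. That the tagged protein or a partner may prefer AT-rich DNA is a hypothesis that stays open, as is a general property of open chromatin; data on other factors are not analysed here.

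The second pattern is the strongest peak of the genome next to the tagged gene. Extra copies of the tagged locus in the transgenic line may raise all regions around CG30403, and the density of pooled regions within 20 kb, the strongest peak left out, lies at percentile 99.0 of all protein-coding genes (0.503 regions per kb against a median of 0.213). The replicate lists give percentiles of 97.1, 99.7 and 99.0. A locus that is simply active in embryos would give the same, so the test does not separate the 2, and the extent and copy number of the transgene are not given in the sources used here. The explanation by copy number stays open for the rank of this peak, and no biological explanation was tested.

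The third pattern is the location of the summits, rich in promoters and poor in coding exons, which are counted here outside promoters only. Low GC is not enough for it: random positions with the same GC in 100 bp lie in coding exons in 4.35% of cases (200 draws, lowest 3.76%) against 0.141% of summits, and at promoters in 11.3% (highest 12.2%) against 46.0%. The 10000 weakest pooled regions lie in coding exons in 5.91% and at promoters in 17.8%. The set of regions that the peak caller could list is thus not enough either, as far as these weak summits are well placed, which is unknown. Low GC could account for part of the coding exon deficit, as 14.1% of unmatched random positions lie there. The weak regions lean the same way as the summits against such positions, of which 11.5% lie at promoters. The set of listed regions could therefore account for part of both. No biological explanation was tested, and chromatin accessibility in embryos is not analysed here.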

How the results depend on the processing

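The merged summits, the dinucleotide shuffles and leaving out the histone list or the off-arm dm3 regions were chosen after seeing the data. So was the comparison of location classes among summits outside promoters. All other alternatives were planned. Of 78 alternatives to the main results, 58 kept direction and side of the threshold or stayed within 1.5 times or 1 SD. The promoter share stayed above chance throughout, from 36.4% with a window of 250 bp to 65.5% with the 1000 strongest peaks. The causes below were not tested unless the construction gives them.

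With 50% fewer regions per list, 2871 peaks were shared by all 3 replicates, and bound genes fell to 2751 with the stronger 50% of peaks and 963 with the 1000 strongest, since fewer peaks were used. The pairwise shared share was 69.0% with a reciprocal overlap and 72.7% with summits within 100 bp, and 81.3 to 86.3% without single replicates. Called lists numbered 8 and 4 with the stronger 50% and the 1000 strongest peaks, 8 with peaks in all 3 replicate lists (10 lists lost their calls, such as vacuolar ATPase and aminoacyl-tRNA synthetases, 1.24 each, and translation factors, 0.84) and 3 with isolated TSSs; motifs called were 6 with the 1000 strongest peaks; 8 7-mers passed against shuffles. The mean rank at CG30403 was 11785 with no margin, where replicate 1 alone kept its rank of 2159, and 370 within 2R. The X log2 odds ratio was -0.24 with the stronger 50% (exact p = 0.0055), -0.70 with the 1000 strongest, -0.025 with peaks in all 3 lists, -0.0064 with a window of 250 bp, -0.0076 to 0.038 without single replicates, and 0.16 with 1000 bp (p = 0.027).

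Of 363 alternatives to the list results, 261 kept direction and side of the threshold, 69 fell short of it, 5 passed it and 28 turned direction; of 200 for the motifs these were 143, 30, 5 and 22. The 5 lists that passed were the proteasome (1.16, adjusted exact p = 0.020), oxidative phosphorylation (0.74, 0.049) and neuronal genes (-3.80, 0.0097) with 250 bp, and gap (-3.44, 0.038) and chorion genes (-2.42, 0.034) with 1000 bp. No list called in the main test turned direction. The following, none of them called in the main test, did (log2 odds ratios): proteasome (-0.032 and -0.47 with the stronger 50% and the 1000 strongest), segment polarity (-0.91, -0.89, then -0.41 with peaks in all 3 lists, -0.50 to 0.090 without single replicates), E(spl) (0.74, 1.83, 0.38; 0.22 with 1000 bp, 0.54 isolated, 1.21 in blocks, 0.15 to 0.29 without single replicates), muscle (0.34, 1.03), glial (0.81 with the 1000 strongest, 0.96 with 1000 bp, 0.72 isolated, -0.54 to 0.98 without single replicates), chorion (0.38 with the 1000 strongest), Hox (0.28 with peaks in all 3 lists, 0.19 isolated, -0.89 to 0.19 without single replicates) and ecdysone (-0.44 with 250 bp). Motifs that turned (log2 ratio of discordant peaks) were M1BP (-0.12, -0.65) and DRE (-0.21 with the 1000 strongest), Tramtrack (0.39, 0.24, 0.26; 0.026 merged, 0.086 with 25 bp, 0.064 to 0.16 without single replicates), Dorsal (0.096, 1.22, 0.052) and Pho (0.31 with the 1000 strongest). Against shuffles GAGA (1.19), CAGCTG (1.58), initiator (0.099), Grainyhead (0.20), Bicoid (-0.47), Dorsal (2.06) and the CA repeat (1.37) turned.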

Other observations

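The comparison of motifs between strong and weak peaks, and the motifs named in it, were chosen after the data were seen; the test of head-to-head promoters was not.

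Of the 20 motifs, 4 passed as less frequent in the strongest peaks, those of DRE, BEAF-32 and M1BP and the CA repeat. The BEAF-32 pattern TCGATA lies inside the DRE pattern TATCGATA, so each DRE site is also counted as a BEAF-32 site. DRE sites were in 1.02% of the centres of the 1956 strongest peaks and 3.37% of the 1956 weakest (adjusted p = 5.1e-06, two-sided Fisher's exact tests over 20 motifs), BEAF-32 sites (TCGATA) in 5.27% and 10.9% (adjusted p = 1.5e-09), M1BP sites in 0.256% and 1.23% (adjusted p = 0.0021), and the CA repeat in 0.358% and 1.89% (adjusted p = 3.2e-05). Bicoid-type sites (TAATCC) went the other way, 4.75% against 2.51% (adjusted exact p = 0.0011). For CTCF sites no difference was detected, 1.43% against 1.69% (adjusted exact p = 0.89), nor for other core promoter motifs: motif 6 (5.16% against 5.73%, adjusted exact p = 0.8), motif 7 (1.84% against 2.1%), the initiator (9.1% in both) and the TATA box (9.92% against 8.69%, adjusted exact p = 0.41). The strongest centres were also lower in GC, 30.8% against 34.5%, which these counts do not adjust for.

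Among other gene types, 300 of 3261 noncoding RNA genes (9.2%) had a summit within 500 bp of a TSS, with 7 of 32 small nuclear RNA genes (21.9%, 95% exact interval 9.28 to 39.97%), 18 of 290 tRNA genes (6.21%), 17 of 269 small nucleolar RNA genes (6.32%) and 117 of 5809 transposable elements (2.01%). These shares include peaks of neighbouring protein-coding promoters.

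A hypothesis was that head-to-head promoters are bound more often than 2 separate ones. Of 2016 pairs of protein-coding genes that point away from each other with 5' ends within 1000 bp, and with no other such end nearby, 1098 had a summit (54.5%, 95% exact interval 52.3 to 56.7%). Single promoters had 1260 of 8252 (15.3%), from which 28.2% would follow for 2 independent promoters. Head-to-head arrangement may therefore go with binding, but genes of general cell maintenance could be more frequent in such pairs, and the test did not separate the kind of gene from the arrangement.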
